A study of Mus musculus with 11 samples.

How the data were processed

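For each library RNA was taken from 1 hippocampus, and its polyadenylated part was sequenced after a strand-marking (dUTP) library preparation, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17.1.14 and the genome build mm10. The aligner, the counting tool, the annotation and whether counting used the strand are not given in the sources used here. The deposited values are whole-number counts per Ensembl gene, not normalized, and are used as the authors deposited them. The table held 30681 genes, of which 30566 matched a symbol and 115 did not. Coordinates are from GENCODE M21, which uses the build mm10.

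Groups were taken from the genotype in the labels: 6 libraries of the conditional Dclk3 knockout and 5 of the wild type, aged 6 months. The total count was 24001828 to 35674490 per library. No 2 libraries of a group were alike within sampling noise, since the smallest chi-square per degree of freedom among replicate pairs was 5.70.

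Genes with low counts were removed with filterByExpr and the other 16587 were scaled by TMM factors. Levels are given in the usual CPM unit, computed here from the deposited counts relative to the TMM-scaled library totals. The main test was edgeR's 2-sided quasi-likelihood F test of the genotype, robust, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 9.56%. The median standard error of a log2 fold change was 0.08. Standard errors were taken from the fold change and its F statistic, and intervals are at 95%. A set of 53 gene lists was fixed before the data were examined. Of their 1134 genes 1101 were tested. The 52 lists with at least 5 tested members were tested by camera on log2 CPM values (prior count 2) with a preset correlation of 0.01. A list score is the mean over members of the log2 CPM centred over the 11 libraries, compared by exact permutation over 462 splits. Intervals of list medians come from 2000 bootstrap draws of the members.

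The rule for named genes was fixed in advance. It takes Dclk3, Dclk1, Dclk2 and Dcx, then up to 12 genes per direction among those past the threshold, or, where fewer pass, the genes of smallest unadjusted p up to 6 per direction. In each list described it takes up to 4 members of smallest p. Some of the members it takes are not named in this report.

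The sex of each library was read from Xist and 4 Y-linked genes. The alternatives were other scaling factors, other filters, the replicate number as a block, limma-voom with quality weights, 1 surrogate variable (sva), DESeq2, each library left out, an estimated correlation, fry and voom values for the lists. A sex term and the 8 male libraries, each also with an estimated correlation, were added after the data were seen. R 4.3.3 was used with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

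The tests were tried on simulated counts for 6 against 5 libraries with 200 changed genes, of which 198 were among the 16457 tested, and 22 further tested genes of 1 shifted list, that of immediate early genes. edgeR recovered 44%, 72%, 92% and 96% of the 50 genes changed 1.25-, 1.5-, 2- and 3-fold, and called 10 of 16237 unchanged genes. DESeq2 recovered 48%, 76%, 92% and 96% and called 25 unchanged genes. Each simulated gene varied independently of the others, and no difference by sex was built in. These shares therefore need not hold for the real libraries, where members of lists moved together.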

Results

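Gene expression was measured by RNA sequencing of polyadenylated RNA from the hippocampus of mice aged 6 months. The hippocampus is the part of the forebrain that holds the dentate gyrus and the CA fields. The series set mice with a conditional knockout of Dclk3, which encodes a doublecortin-like kinase, against wild-type (WT) mice. A conditional knockout (cKO) is a deletion limited to cells that express a recombinase. Neither the recombinase line nor the deleted part of the gene is stated in the sources used here. There were 6 cKO and 5 WT libraries, each from 1 hippocampus. The labels do not say that the libraries came from different animals, so p-values measure only the spread between these samples. The deposited table held counts for 30681 genes. The total count per library ran from 24001828 to 35674490, with a mean of 31225061 ± 4546471 in the cKO libraries (SD, n = 6) and 31664995 ± 1623758 in the WT libraries (SD, n = 5). The total did not differ between the groups beyond its spread (2-sided exact permutation p = 0.85).

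The first question was whether the targeted gene was lower in the libraries labelled cKO. Dclk3 (ENSMUSG00000032500, chromosome 9, 111439081 to 111489118, plus strand, mm10) had 20.1 ± 3.44 CPM in the libraries labelled cKO (SD, n = 6) and 22.4 ± 3.31 CPM in the WT libraries (SD, n = 5). The values of replicates 1 to 6 labelled cKO were 15.5, 21.1, 21.1, 25.7, 18.2 and 19.2 CPM. Those of WT replicates 1 to 5 were 19.6, 21.03, 22.3, 28.1 and 21.1 CPM. The log2 fold change was -0.15 ± 0.12 (SE), with a 95% interval from -0.41 to 0.10, and did not pass the test (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.727). The gene has 5 exon blocks and shares no exon bases with another annotated gene, and the table gives 1 count for the whole gene. The count therefore does not show whether part of the gene was deleted. Since the lower mean of Dclk3 did not pass the test, the group is called "labelled cKO" from here on, and every direction below is that of the labels.

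The other doublecortin-family genes also stayed within the spread. Dclk1, a kinase that binds microtubules, had 612 ± 33.7 CPM in the libraries labelled cKO and 597 ± 33.4 CPM in WT (SD, n = 6 and 5). Its log2 fold change was 0.03 ± 0.05 (SE). Dclk2 had a log2 fold change of 0.05 ± 0.05 (SE), and Dcx, a microtubule-associated protein of immature neurons, one of -0.05 ± 0.15 (SE). The signs of Dclk1 and Dclk2 turned in the 8 male libraries, to -0.03 for each gene.

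**Figure D1:**
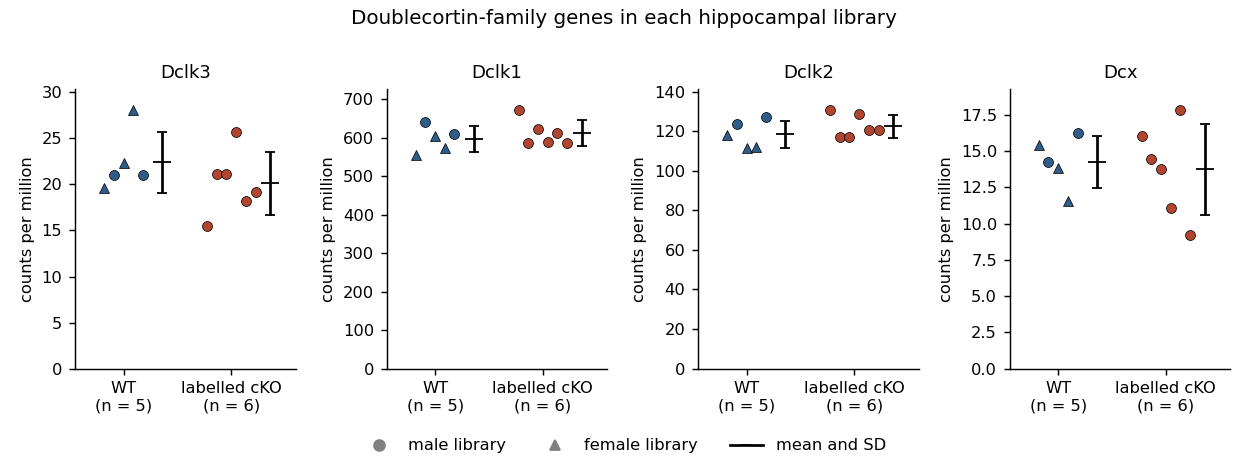
CPM of Dclk3, Dclk1, Dclk2 and Dcx in each library, by group, with the mean and SD beside the points and each axis from 0. Circles are male and triangles female libraries by their sex-linked transcripts. Dclk3 ran from 15.5 to 25.7 CPM in the libraries labelled cKO and from 19.6 to 28.1 CPM in WT.

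The sexes were not balanced. Xist, the RNA that silences an X chromosome in females, had 490 to 721 CPM in WT replicates 1, 3 and 4 and 1.23 to 10.99 CPM in the other 8 libraries. The sum of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y was 0.904 to 3.54 CPM in those 3 libraries and 97.4 to 121.5 CPM in the other 8. By these transcripts all 6 libraries labelled cKO were male, and WT held 3 female and 2 male libraries. No comparison within females was possible. Values from the 6 labelled cKO against the 2 WT male libraries are given beside the results they bear on, as a comparison chosen after the data were seen.

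**Figure D2:**
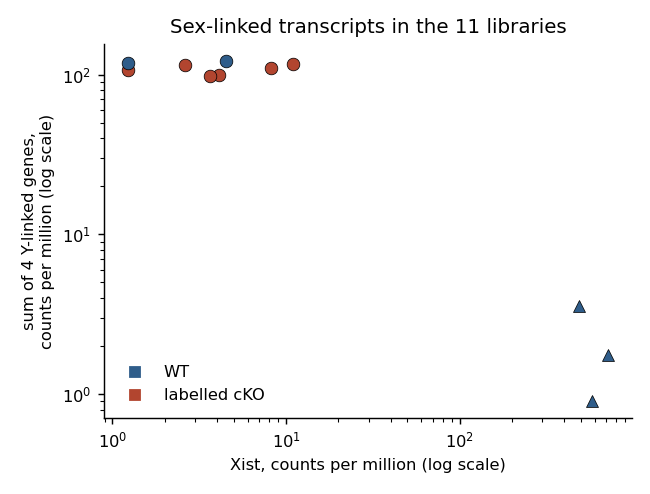
Xist (x axis, CPM, log scale) against the sum of Ddx3y, Uty, Kdm5d and Eif2s3y (y axis, CPM, log scale), with 1 point per library. WT replicates 1, 3 and 4 lie at 490 to 721 CPM of Xist, and the 6 libraries labelled cKO lie with the other 2 WT libraries at 97.4 to 121.5 CPM of the Y-linked sum.

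The main comparison asked which genes differed between the genotypes. Dusp1, a phosphatase that switches off MAP kinases, came nearest to the threshold, with 11.4 ± 1.05 CPM in the libraries labelled cKO and 17.9 ± 2.84 CPM in WT (SD, n = 6 and 5). Its log2 fold change was -0.66 ± 0.10 (SE; edgeR, adjusted p = 0.0559), and all 6 libraries labelled cKO lay below every WT library. The other genes with the smallest p among the lower ones were Zic1, a transcription factor (-0.46 ± 0.09), Btg2, an antiproliferative early-response gene (-0.57 ± 0.11), Adamts1, a secreted metalloprotease (-0.42 ± 0.08), Ier2, an early-response gene (-0.54 ± 0.11), and Fance, a gene of DNA crosslink repair (-0.29 ± 0.06; log2 ± SE). Among the higher ones they were Cybrd1, an iron-reducing enzyme (0.67 ± 0.12), Wdr44 (0.26 ± 0.05), Itgav, the integrin alpha V subunit (0.24 ± 0.05), Pcdhb15, a clustered protocadherin (0.50 ± 0.11), Prlr, the prolactin receptor (0.66 ± 0.15), and Gabra2, a GABA-A receptor subunit (0.19 ± 0.04; log2 ± SE). None of these 12 genes passed edgeR's test over all genes, where the 11 other than Dusp1 had adjusted p from 0.26 to 0.30, and all 12 were called by DESeq2. The 6 higher genes each lay above every WT library in all 6 libraries labelled cKO. Pcdhb15 belongs to a cluster of similar genes, so its count is uncertain.

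At an adjusted p under 0.05, edgeR called 0 genes higher and 0 lower among 16587 tested. At an unadjusted p under 0.05 there were 637 higher and 887 lower genes, 1524 in all. DESeq2 called 61 genes, 30 higher and 31 lower. With a sex term DESeq2 called 3 (Cybrd1 and Krt2 higher, A830036E02Rik lower) and on the 8 male libraries 2 (Cybrd1 and Krt2), where Krt2 and A830036E02Rik are named after their values were seen. Leaving out WT replicate 5 or WT replicate 2, the 2 male WT libraries, makes 3 of the 4 WT libraries left female. Without WT replicate 5, edgeR called 14 genes, all lower, of which 9 belong to the list of immediate early genes. Among these, the log2 fold changes of the 11 libraries shrank in the 8 male libraries from -0.91 to -0.67 (Fos), from -0.66 to -0.52 (Dusp1), from -0.57 to -0.39 (Btg2) and from -0.54 to -0.33 (Ier2). Without WT replicate 2 edgeR called 2 (Aldh1a2 and Slc13a4, lower). Their log2 fold changes shrank in the 8 male libraries from -0.93 to -0.35 and from -0.76 to -0.40. But the 2 male WT libraries differed, and the one left out was the lower one for these genes. Fos was 8.79 CPM in WT replicate 5 and 17.1 CPM in WT replicate 2. Aldh1a2 was 3.13 CPM in WT replicate 2 and 5.90 CPM in WT replicate 5. An effect of sex was therefore not told from that of 1 low library. Without WT replicate 1 edgeR called 1 (Cybrd1, higher).

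Of 52 gene lists tested, 12 were higher and 8 lower as a group in the libraries labelled cKO by camera with a preset correlation of 0.01. None of the 20 was called with an estimated correlation, where the smallest adjusted p was 0.46, and none by fry's directional test, where it was 0.15. Fry's mixed test, which counts changes in either direction and compares no list with other genes, called 7 of the 20 and 1 other list. By edgeR no member of any list passed the gene test over all genes, so the counts of members below are edgeR's, adjusted over the list alone. Of the 61 DESeq2 calls over all genes 26 belong to 1 or more of the lists. Among them are 7 of the 22 immediate early genes (Dusp1, Btg2, Ier2, Fos, Egr1, Egr4 and Junb), Gabra2, Gabrb2, Gabrb1 and Gabrd, the meningeal genes Aldh1a2, Slc13a4, Slc6a13 and Igf2, Zic1, Ramp3, Per1, Nfkbia and Mlc1. DESeq2 with a sex term or on the 8 male libraries called none of these. In the 8 male libraries edgeR's log2 fold changes did not shrink for Gabra2 (0.22), Zic1 (-0.47), Ramp3 (-0.76), Per1 (-0.28) and Mlc1 (0.17). They did for the other genes named here. With 2 WT libraries left there, a lost call alone does not show an effect of sex. Also among the 26 are Xist (-6.12) and the X-linked Kdm6a, of the list of sex-linked transcripts, so the 61 calls hold differences by sex.

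Immediate early genes, which neurons transcribe within minutes of activity, were the list with the smallest p. Of its 22 members 18 had lower and 4 higher values, and the median log2 fold change was -0.42 (95% bootstrap interval over members -0.57 to -0.10; camera, adjusted p = 9.96e-09 with the preset and adjusted p = 0.46 with an estimated correlation). Adjusted over the list alone 12 were lower and 0 higher: Dusp1, Btg2, Ier2, Fos, Egr4, Junb, Egr1, Fosb, Nr4a1, Egr2, Arc and Npas4. Fos, a transcription factor of the AP-1 complex, had 8.09 ± 1.57 CPM in the libraries labelled cKO and 15.3 ± 3.82 CPM in WT (SD, n = 6 and 5), a log2 fold change of -0.91 ± 0.18 (SE). WT replicate 5, a male library, stood with the libraries labelled cKO, with Fos at 8.79 CPM against 15.3 to 18.7 CPM in the other 4 WT libraries. WT replicate 2, the other male, had 17.1 CPM. The mean list score, the average centred log2 CPM of the members, was -0.17 ± 0.07 in the libraries labelled cKO and 0.21 ± 0.23 in WT (SD, n = 6 and 5; 2-sided exact permutation p = 0.0087, Benjamini-Hochberg adjusted over 53 lists 0.23). Against the 2 male WT libraries the score difference was -0.28 (exact permutation p = 0.14, where 28 splits allow no p under 0.036). The list was still called there (median -0.34; camera, adjusted p = 0.00035) and with a sex term (median -0.34; camera, adjusted p = 0.00019), by the preset correlation. The delayed activity-regulated genes, such as Bdnf, had a median of 0.11, the other sign (camera, adjusted p = 0.0286, and adjusted p = 0.71 with an estimated correlation). This call ended without replicate 4 or 6 labelled cKO, or WT replicate 2 or 5 (camera, highest adjusted p = 0.23).

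**Figure D3:**
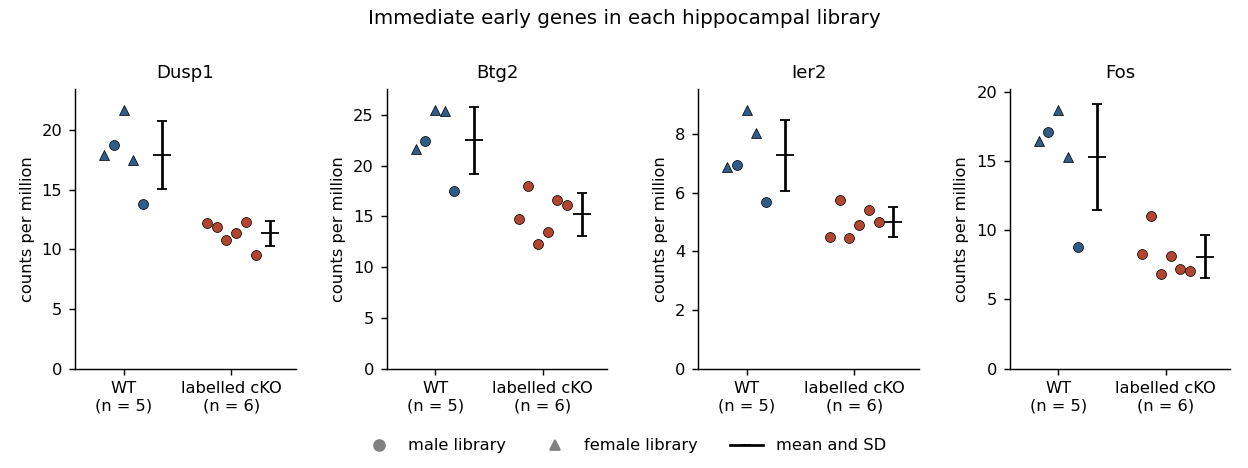
CPM of Dusp1, Btg2, Ier2 and Fos in each library, by group, with the mean and SD beside the points and each axis from 0. Circles are male and triangles female libraries. Fos ran from 6.83 to 11.1 CPM in the libraries labelled cKO, and WT replicate 5 had 8.79 CPM against 15.3 to 18.7 CPM in the other WT libraries.

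Microglial genes, markers of the resident immune cells of the brain, had higher values in all 18 members, with a median log2 fold change of 0.20 (camera, adjusted p = 3.72e-07, and adjusted p = 0.46 with an estimated correlation). Of these 2 were higher and 0 lower adjusted over the list alone. Among them was P2ry12, a purinergic receptor of resting microglia, at 0.19 ± 0.06 (log2 ± SE). The list score was 0.09 ± 0.20 in the libraries labelled cKO and -0.10 ± 0.07 in WT (SD, n = 6 and 5; 2-sided exact permutation p = 0.056), and replicate 2 labelled cKO was highest at 0.41. In the 8 male libraries the median was 0.24 (camera, adjusted p = 2.3e-05), as it was with a sex term (camera, adjusted p = 1.2e-05). Both calls use the preset correlation, and with an estimated one each had an adjusted p of 0.81 (camera). The score difference in the 8 male libraries had an exact permutation p of 0.18. Disease-associated microglia genes had a median of 0.18, with 16 of 20 higher and 0 passing adjusted over the list alone (camera, adjusted p = 0.0021, and adjusted p = 0.71 with an estimated correlation). Axl, a receptor kinase, was at 0.17 ± 0.05 and Spp1 at -0.49 ± 0.17 (log2 ± SE). Without replicate 2 labelled cKO the call on this list ended (camera, adjusted p = 0.063).

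Astrocyte genes had a median of 0.07, with 15 of 18 higher (camera, adjusted p = 0.00153, and adjusted p = 0.46 with an estimated correlation). There were 3 higher and 0 lower adjusted over the list alone: Mlc1, a membrane protein of astrocyte end-feet (0.16 ± 0.05), Gja1, which encodes connexin 43 (0.21 ± 0.06), and Slc1a2, the main glutamate transporter (0.22 ± 0.07; log2 ± SE). Reactive astrocyte genes had a median of 0.31, with 15 of 20 higher and 0 passing adjusted over the list alone (camera, adjusted p = 0.00593, and adjusted p = 0.71 with an estimated correlation). The 8 male libraries gave a median of 0.54 (camera, adjusted p = 0.00035 with the preset, and adjusted p = 0.81 with an estimated correlation). The score difference there had an exact permutation p of 0.29. Osmr, a cytokine receptor, was at 0.36 ± 0.11 and S100a10 at 0.40 ± 0.16 (log2 ± SE). The reactive list score reached 0.68, 0.22 and 0.77 in replicates 2, 4 and 6 labelled cKO and 0.37 in WT replicate 1, and lay below 0 in the other 7 libraries. Without replicate 2 or 6 labelled cKO, or WT replicate 2 or 5, the call on the reactive list ended (camera, highest adjusted p = 0.21).

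GABA receptor subunits had a median of 0.10, with 11 of 15 higher (camera, adjusted p = 0.00184, and adjusted p = 0.46 with an estimated correlation). The test adjusted over the list alone gave 3 higher and 1 lower. Gabra2 had 292.5 ± 12.1 CPM in the libraries labelled cKO and 256 ± 9.25 CPM in WT (SD, n = 6 and 5). Gabrb2 was at 0.17 ± 0.04, Gabrb1 at 0.17 ± 0.04 and Gabrd, the subunit of extrasynaptic receptors, at -0.34 ± 0.08 (log2 ± SE). In the 8 male libraries the median was 0.05 and the list was no longer called (camera, adjusted p = 0.1).

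Genes of meningeal and perivascular fibroblasts had a median of -0.22, with 12 of 15 lower (camera, adjusted p = 0.000596, and adjusted p = 0.53 with an estimated correlation). There were 5 lower and 0 higher adjusted over the list alone: Slc13a4, a sulfate transporter (-0.76 ± 0.16), Igf2, a growth factor (-0.56 ± 0.12), Aldh1a2, a retinoic acid synthesis enzyme (-0.93 ± 0.21), Slc6a13, a GABA transporter (-0.62 ± 0.16), and Slc22a6 (log2 ± SE). In the 8 male libraries the median was -0.10 and the list was no longer called (camera, adjusted p = 0.87), with Slc13a4 at -0.40, Igf2 at -0.30, Aldh1a2 at -0.35 and Slc6a13 at -0.11. The 2 male WT libraries lay far apart, with list scores of -0.34 in replicate 2 and 0.19 in replicate 5. The female WT scores were 0.29 to 0.50, and those of the libraries labelled cKO -0.23 to -0.08. The smaller male median therefore does not tell sex from the low values of WT replicate 2. Thalamic genes, fixed as a check on dissection, had a median of -0.05 (camera, adjusted p = 0.00593, and adjusted p = 0.46 with an estimated correlation). The test adjusted over the list alone gave 4 lower and 0 higher, among them Zic1 and Ramp3 (-0.59 ± 0.13, log2 ± SE). Without WT replicate 2 the call on this list ended (camera, adjusted p = 0.063). The 8 male libraries gave a median of -0.15 (camera, adjusted p = 0.00035 with the preset, and adjusted p = 0.54 with an estimated correlation). The score difference there had an unadjusted exact permutation p of 0.036.

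Histone deacetylases and sirtuins, which remove acetyl groups, had a median of -0.06, with 15 of 22 lower (camera, adjusted p = 0.00593, and adjusted p = 0.46 with an estimated correlation). Adjusted over the list alone 2 were lower and 0 higher, Sirt4 at -0.37 ± 0.10 and Hdac7 at -0.28 ± 0.08 (log2 ± SE). Its score lay below every WT library in all 6 libraries labelled cKO (2-sided exact permutation p = 0.0043, adjusted 0.23). The gap was narrow, from 0.0022 in replicate 1 labelled cKO to 0.0023 in WT replicate 1. The difference in the 8 male libraries was -0.11 (exact permutation p = 0.036, unadjusted, the smallest that 28 splits allow). Histone methyltransferases and demethylases had a median of -0.05, with 31 of 44 lower and 0 passing adjusted over the list alone (camera, adjusted p = 0.0242, and adjusted p = 0.71 with an estimated correlation). That call ended without replicate 2, 3 or 4 labelled cKO, or WT replicate 2 or 5 (camera, highest adjusted p = 0.1). The member of smallest p, the X-linked Kdm6a, went from -0.41 to -0.08 in the 8 male libraries. Kdm5c, also X-linked, went from -0.19 to 0.04. The list median there was -0.06 (camera, adjusted p = 0.0039 with the preset, and adjusted p = 0.81 with an estimated correlation). Glucocorticoid-induced genes had a median of -0.09 (camera, adjusted p = 0.0494, and adjusted p = 0.46 with an estimated correlation). Adjusted over the list alone 2 were lower and 0 higher, Per1, a clock gene (-0.25 ± 0.05), and Nfkbia, an NF-kappa-B inhibitor (-0.29 ± 0.07; log2 ± SE). The glucocorticoid call ended without any 1 of replicates 1 to 5 labelled cKO or WT replicates 1 to 3 (camera, highest adjusted p = 0.15), and in the 8 male libraries (camera, adjusted p = 0.34).

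Of the other called lists, the higher ones were microtubule and tau genes (0.06), the unfolded protein response (0.12), nuclear-encoded oxidative phosphorylation subunits (0.04), lysosome and autophagy genes (0.05), red blood cell genes (0.14) and postsynaptic scaffolds (0.04). Lower lists were dentate granule cell genes (-0.09) and genes of pericytes and smooth muscle (-0.12). Single libraries ended 5 of these calls (camera): replicate 6 labelled cKO or WT replicate 5 that on oxidative phosphorylation (highest adjusted p = 0.071), replicate 4 labelled cKO or WT replicate 2 that on lysosome and autophagy genes (0.076), replicate 1 or 4 labelled cKO or WT replicate 1 or 3 that on postsynaptic scaffolds (0.28), replicate 3 or 4 labelled cKO or WT replicate 2, 3 or 4 that on dentate granule cells (0.21), and replicate 2, 3 or 4 labelled cKO or WT replicate 1 or 4 that on pericytes and smooth muscle (0.15), each when left out. These lists held, adjusted over the list alone, Alas2 (red blood cells, higher) and Anpep (pericytes, lower). With an estimated correlation their adjusted p ran from 0.46 to 0.73 (camera). In the 8 male libraries 13 of the 20 lists were still called in their direction, and the lists lost included red blood cell genes, dentate granule cell genes and pericytes and smooth muscle, while postsynaptic scaffolds turned sign to -0.01. The other 32 lists were not called in the 11 libraries, with medians from -0.19 to 0.12. Of them 4 were called in the 8 male libraries (camera): interferon-stimulated (median 0.54, adjusted p = 0.032), heat shock (0.09, adjusted p = 0.0059) and cholesterol synthesis genes (0.09, adjusted p = 0.036) higher and circadian genes (-0.07, adjusted p = 0.02) lower. These are calls with the preset correlation. With an estimated one no list was called in the 8 male libraries (camera, smallest adjusted p = 0.54, and 0.81 to 0.92 for these 4), and the exact permutation p of these 4 list scores ran from 0.14 to 0.68. With a trend on GC content and transcript length removed, each of the 20 lists kept over 50% of its median, but for 4 the interval of that share over members reached below 50%: histone deacetylases and sirtuins, thalamic genes (59.7% kept, -333% to 109%), dentate granule cells, and pericytes and smooth muscle.

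**Figure D4:**
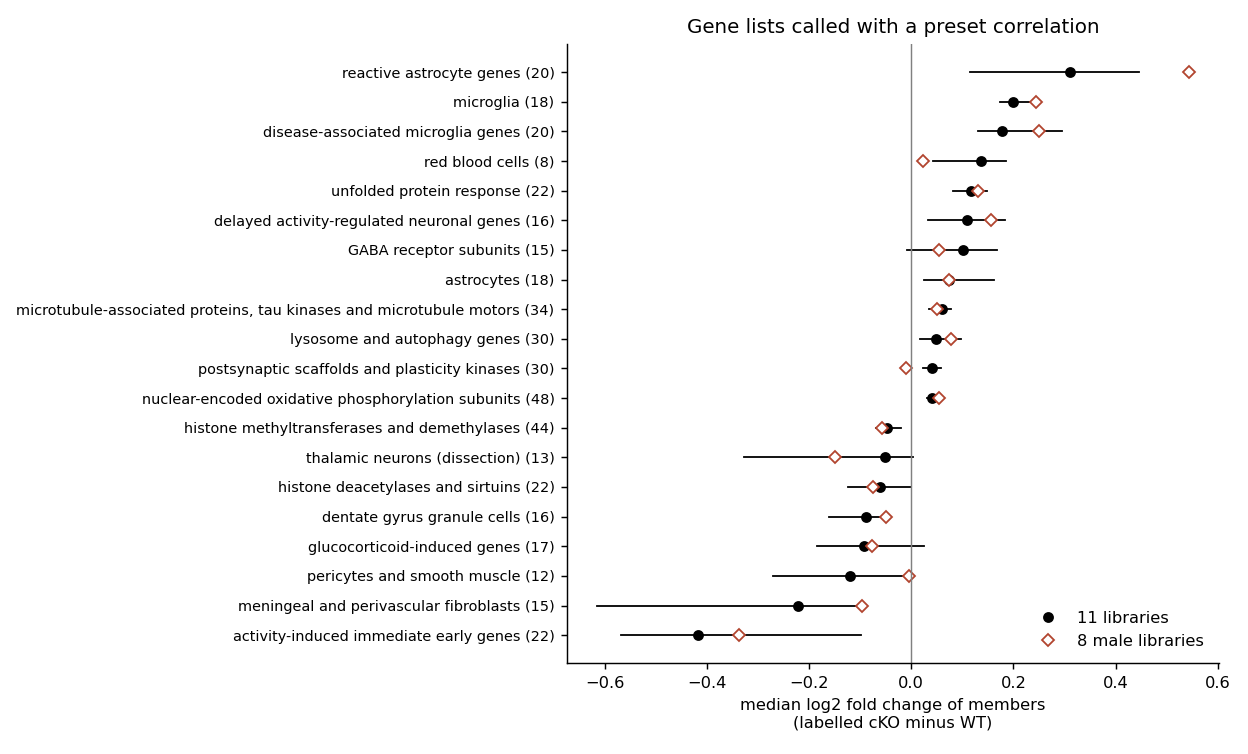
Median log2 fold change (x axis, labelled cKO minus WT) of the members of the 20 lists called with a preset correlation, with the number of tested members in parentheses. Black points are the 11 libraries with 95% bootstrap intervals over members, and open diamonds the 8 male libraries. The median of meningeal and perivascular fibroblast genes was -0.22 in the 11 and -0.10 in the 8 male libraries.

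Counting by strand is not stated, so reads of overlapping genes on opposite strands cannot be told apart. Of the 44 genes selected for description 15 share exon bases with another annotated gene. Among them are Igf2, which overlaps Gm49394 (3596 bases), and Itgav, which overlaps Gm13684 (634 bases), and the counts of these genes are uncertain.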

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

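The tests of sex, of the share of neurons, of noise and of a partial deletion, the interval used for the GC and length trend, the number of splits used with DESeq2 and the count of splits by sex were chosen after the results were seen.

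Immediate early genes had lower values in the libraries labelled cKO. With a trend on GC content and transcript length removed, 90.4% of the list median was kept (95% interval of that share over members 82.7% to 96.4%), which argues against this trend as the whole cause. Sex stays open: the list was still called in the 8 male libraries with the preset correlation (camera, adjusted p = 0.00035), but the 2 male WT scores lay far apart (0.40 and -0.19), and the score difference with sex in the model, -0.277, had a 95% interval over libraries of -0.58 to 0.02. Genotype, or what the mice did before sampling, may also lie behind it, and these were not tested.

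Microglial genes had higher values in the libraries labelled cKO. A lower share of neurons would raise the other non-neuronal markers alike. The intervals over members of all 6 other non-neuronal lists lay below that of microglia in the 11 libraries. In the 8 male libraries 5 of the 6 did (all but the meningeal list), so those lists had a smaller rise than microglia or none. Astrocyte genes did rise, with an interval over members of 0.03 to 0.16 in the 11 libraries. In the 8 male libraries the interval of endothelial genes, 0.009 to 0.12, also lay above 0. But intervals over members leave out the spread between libraries, where microglial members moved together (estimated correlation 0.45). The test therefore does not decide on the share of neurons. This test replaced an earlier one, the number of those lists with medians below 0 beyond their spread, which was 2 over the 11 libraries and 0 over the male ones. With sex in the model the score difference was 0.242, with a 95% interval over libraries of -0.06 to 0.54 that reaches both signs. The list was still called in the 8 male libraries with the preset correlation (camera, adjusted p = 2.3e-05). Male minus female in WT was -0.09. Its interval was -0.42 to 0.25 with the spread of all 11 libraries and -0.25 to 0.08 with that of WT alone. As 2 WT libraries are male too, sex alone would need a male minus female difference well above the 0.19 between the groups. That lies beyond both intervals, but the 0.19 has its own spread between libraries, which this comparison leaves out. As the interval with sex in the model reaches both signs, these values do not decide on sex as the whole cause. Sex stays open, and a change in microglia with genotype may be involved but was not told from the spread between libraries.

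Dclk3 counts had a lower mean in the libraries labelled cKO, a log2 fold change of -0.15 that did not pass the test. Noise that hides a loss of most of the RNA is argued against by the lower bound of the 95% interval, -0.408 on the log2 scale. For a swap of libraries between the groups, the lowest of the 11 values had a Dixon ratio of 0.217, under the 95% critical value. That value was 15.5 CPM in replicate 1 labelled cKO, not in a WT library. The ratio looks for 1 lone low value, and several low libraries would hide each other, so it does not decide on a swap. A deletion of part of the gene that leaves the rest transcribed may explain the counts. It stays open, since the gene has 5 exon blocks and counts per exon were not used here.

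The 11 libraries were also split in 100 ways into 6 and 5, the real split included. For genes called by edgeR the split count decides nothing, since all 100 splits reach the real count of 0, and the highest other gave 6. For genes at an unadjusted p under 0.05, 7 of 100 splits gave 1524 or more, and the highest other gave 2154. For called lists, 10 of 100 gave 20 or more, and the highest other gave 29. For DESeq2, 6 of 100 gave 61 or more calls, and the highest other gave 187. Chance cannot be excluded for these last 3 counts. For DESeq2 the share depended on how many splits were drawn. Only the real one of the first 30 reached 61 calls (3.33%), and 4 of the first 60 did (6.67%). The share from 30 is under the 5% limit used here, but it is the smallest that 30 splits can give. The number was raised to 60 after the result for 30 had been seen, and then to the 100 used for edgeR. A split with 187 calls, several times the real count, points to a structure among the samples. That split put the 3 female libraries on one side, as did 5 of the 6 splits with 61 or more calls (the real one among them) and 17 of all 100. The splits were drawn without regard to sex, so a difference by sex may add to these counts.

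A single library lay far from its group in 7 of 132 groups of values checked, where chance gives about 5%, or 6.6. Fos was 11.1 CPM in replicate 2 labelled cKO, against 6.83 to 8.25 CPM in the others. Slc13a4 was 3.47 CPM in replicate 1 labelled cKO, against 2.43 to 2.81 CPM. Hdac7 was 34.4 CPM in WT replicate 5, against 25.6 to 27.7 CPM. Nfkbia was 20.3 CPM in WT replicate 5, against 22.8 to 23.5 CPM. Penk was 26.6 CPM in WT replicate 3, against 32.9 to 34.6 CPM. The score of the unfolded protein response was 0.35 in replicate 6 labelled cKO, against -0.11 to 0.05, and that of glucocorticoid-induced genes was 0.10, against -0.09 to -0.02.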

How the results depend on the processing

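A sex term and the 8 male libraries, each also with DESeq2 and with an estimated correlation, were chosen after the data were seen. A sex term had been planned only if both sexes were present in both groups, which did not hold. The edgeR count of 0 higher and 0 lower genes held with DESeq2's size factors, upper-quartile factors, a filter of 1 CPM in 5 libraries, voom, 1 surrogate variable, the sex term and the 8 male libraries. With no filter on low counts it was 1 higher and 2 lower, with DESeq2 30 and 31, with DESeq2 and a sex term 2 and 1, and with DESeq2 on the 8 male libraries 2 and 0. With single libraries left out it ran from 0 to 1 higher and from 0 to 14 lower. DESeq2 gave no adjusted p for 15673 of its 29986 genes. The cause of these differences was not tested.

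For the lists, 12 higher and 8 lower became 0 and 0 with an estimated correlation (in the 11 libraries, with the sex term and in the 8 male libraries) and 0 and 0 with fry, and 12 and 5 with the sex term and with the 8 male libraries. With single libraries left out they ran from 10 to 15 higher and from 4 to 8 lower. The other alternatives gave 12 to 16 higher and 7 to 9 lower, the block apart. Calls on 9 of the 20 lists held with every single library left out. Postsynaptic scaffolds turned from 0.04 to -0.013 with the sex term and to -0.010 in the 8 male libraries.

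Dclk3 stayed below 0 and short of the test under all 23 alternatives, from -0.24 to -0.06. Of 1012 values of the 44 named genes under the alternatives, 1001 kept their direction. Dclk1 turned to -0.033 and Dclk2 to -0.035 with the sex term, to -0.031 and -0.033 in the 8 male libraries, to -0.030 and -0.032 with DESeq2 and a sex term, and to -0.028 and -0.031 with DESeq2 on the 8 male libraries. Dcx ran from -0.14 to 0.036 with single libraries left out and was 0.033 with the replicate block.

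Equal replicate numbers did not pair the samples: the correlations of their deviations from the group means ran from -0.316 to 0.213, and only number 4 had its best partner in its own number on both sides. With the replicate block on 10 libraries 0 genes were called higher and 0 lower, with 9 lists higher and 6 lower. No scaling moved the median of all genes by over 0.1.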

Other observations

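Of 19 neuropeptide precursors tested, 3 passed when adjusted over the list alone. Penk, which encodes enkephalins, was higher (46.7 ± 10.2 CPM in the libraries labelled cKO and 32.3 ± 3.31 CPM in WT, SD, n = 6 and 5). Cort, which encodes cortistatin (-0.70 ± 0.18), and Pdyn, which encodes dynorphins (-0.51 ± 0.14, log2 ± SE), were lower. The list was not called (camera, adjusted p = 0.869). None of the 3 passed edgeR's test over all genes, where DESeq2 called Penk, and in the 8 male libraries their log2 fold changes were 0.48 (Penk), -0.37 (Cort) and -0.23 (Pdyn). Among CA2 and CA3 pyramidal cell genes, adjusted over the list alone, Coch (-0.65 ± 0.17), Cdh24 (-0.33 ± 0.11) and the neurotrophin Ntf3 (-0.47 ± 0.16, log2 ± SE) were lower, and the list was not called (camera, adjusted p = 0.0929). In the 8 male libraries these 3 were at -0.23, -0.41 and -0.20.

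Interferon-stimulated genes varied between libraries within both groups. The list score was 1.35 in replicate 2 labelled cKO and 0.76 in WT replicate 1, and -0.70 in replicate 1 labelled cKO. The list was not called in the 11 libraries (median 0.12; camera, adjusted p = 0.851). In the 8 male libraries it was called higher (median 0.54; camera, adjusted p = 0.032), but its score difference of 0.27 lay within the spread (exact permutation p = 0.68). Genes near Dclk3 on chromosome 9 had a median of -0.04 and were not called (camera, adjusted p = 0.151).

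The 3 female WT libraries held some counts of the 4 Y-linked genes: 29 in replicate 1, 60 in replicate 3 and 119 in replicate 4. Their sums in CPM were 0.818%, 1.59% and 3.21% of the mean of the 8 male libraries.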
